A study of Homo sapiens with 14 samples.

How the data were processed

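The data are bulk RNA sequencing counts of human primary CD8+ T cells, taken from peripheral blood mononuclear cells and cultured for 48 h, in 14 libraries from 6 donors. Reads were counted per gene on the hg38 build with HTSeq, and DESeq2 was also named, per the labels. Versions, aligner, annotation release, strand setting and filters were not given in the sources used here. The deposited table holds the authors' raw counts, 1 column per library and no normalization, with 44584 gene symbols of which 24171 had any count in these libraries. Total counts per library lay between 6543797 and 10318778, so a gene at the floor of 3 counts sat below 1 CPM (counts scaled to a common library size). Such limits cover counting error only.

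Each library was assigned to its treatment group and donor from the labels: 4 libraries of OKT3, 5 of OKT3_MAdCAM_RA and 5 of OKT3_MAdCAM_RA_TGFb. The replicate number of a library is the number of its donor, and 3 donors have all 3 treatments. The labels name 3 sequencing runs: run 2 (donors 4 and 6), run 3 (donors 7 and 8) and run 4 (donors 10 and 12, without OKT3). Same-numbered libraries come from the same donor, per the labels, so the numbers pair the samples. Over 11 same-donor pairs the deviations from the group means correlated with a median of 0.171 (range 0.0731 to 0.414), against -0.0268 for 10 pairs of different donors in the same run and -0.0344 for 44 pairs across runs. The main model nevertheless used group means alone, and the donor as a block (the replicate block, with 423 higher and 426 lower genes at the TGFb step against 163 and 90 without it) was an alternative.

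Genes on the sex chromosomes that could tell a person's sex, HLA genes and receptor gene segments were removed (1110 symbols, 0.247 to 0.807% of a library's counts). A further 5082 symbols with a numbered copy suffix were kept as separate genes and hold 0.154 to 0.542% of counts. Counts were normalized with TMM and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 13015 genes. One model of the 3 group means over all 14 libraries was fitted with edgeR's robust quasi-likelihood method (11 residual degrees of freedom), and each comparison was tested with its two-sided F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression is given as CPM on TMM-scaled library sizes, mean ± SD over the libraries of a group, and log2 fold changes are given ± their standard error from the fit. No 2 libraries of a group were duplicates (smallest chi-square per degree of freedom 17.6 over 26 pairs). On counts simulated with this design, the pipeline found 23.2, 19.4 and 26.5% of planted changes of 2-fold and 69.1, 73.7 and 69.7% of 4-fold for the 3 comparisons, with 3, 7 and 5 false calls. It also called the planted gene list (camera). The genes were simulated independently, so this does not test camera on correlated genes.

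Gene lists were tested as sets with camera (two-sided, preset inter-gene correlation of 0.01, adjusted over the lists). Of 30 lists, 27 had at least 5 tested members. They cover tissue-resident memory (TRM) genes higher and lower than in circulating cells, TGF-beta response, retinoic acid response, gut homing, cytotoxic effectors, T cell activation, inhibitory receptors and exhaustion, naive and central memory genes, cytokines and chemokines, cell cycle, interferon response, glycolysis and hypoxia, oxidative phosphorylation, cholesterol and lipid synthesis, the ATF4 amino acid response, type 17, type 2 and regulatory T cell genes, markers of CD4 T cells, B cells, NK cells and innate-like T cells, T and CD8 identity genes, nuclear noncoding RNAs, heat shock and dissociation genes, and apoptosis and p53 targets. The monocyte and dendritic cell markers (4 of 23 members tested), the platelet and erythroid markers (4 of 17) and the mitochondrial messenger RNAs (0 of 13 in the table) were not tested as sets.

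The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison, the 12 genes with the largest log2 fold change in each direction among those past the threshold with at least 5 CPM in the higher group and the same sign in every donor pair, up to 4 members of each list with the smallest adjusted p past the threshold, and 33 genes chosen for the biology of the treatments. The text gives part of the genes that the rule allows, and 2 genes are not reported here. Of the 33 genes, 28 were tested. The other 5 had too few counts: ZNF683 45 counts over all libraries, PDCD1 3, CD4 3, and 0 for CYP26B1 and TNF (37 on copies of TNF).

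Alternatives were the donor block, the sequencing run as a covariate, RLE size factors, DESeq2 1.42.0, limma voom 3.58.1 with the donor as a random effect (consensus correlation 0.222), no filter or a stricter filter (10 CPM in at least 4 libraries), a fit of only the 2 groups compared, the 3 complete donors with the block, an estimated inter-gene correlation, fry, and leaving out each library in turn. After the data were seen, 2 more were added: leaving out RNR1, RNR2, MALAT1 and TALAM1, and leaving out the 2 libraries that lay apart from their groups on the principal components. Coordinates are those of the RefSeq annotation of GRCh38.p14, which matched 41645 of the 44584 symbols. Since the counting strand was not given, the count of a gene that overlaps another counted gene is uncertain. The text marks genes given with values where the other gene holds over 10% of their counts.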

Results

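RNA from human bulk CD8+ T cells was sequenced after 48 h of culture under 3 treatments. The cells were stimulated through the T cell receptor complex with OKT3, an antibody against CD3 (4 libraries). They also received MAdCAM, the gut addressin bound by integrin α4β7, with retinoic acid (OKT3_MAdCAM_RA, 5 libraries), or the same with TGF-beta added (OKT3_MAdCAM_RA_TGFb, 5 libraries). The series concerns the induction of tissue-resident memory T cells, which stay in tissues such as the gut lining instead of recirculating. The replicate number of a library marks its donor, of whom there were 6. Total counts per library were 8113776 ± 1025092 in OKT3 (SD, n = 4), 8456366 ± 1183166 in OKT3_MAdCAM_RA (n = 5) and 8682443 ± 1283557 in OKT3_MAdCAM_RA_TGFb (n = 5). They ranged from 6543797 to 10318778 over the 14 libraries. Two-sided exact permutation tests of total counts gave p = 0.651, 0.77 and 0.492 for the 3 comparisons.

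The OKT3 libraries differed from the others in their RNA content. RNR2, the large mitochondrial ribosomal RNA, took 4.95 ± 1.12% of counts in OKT3, 1.72 ± 0.365% in OKT3_MAdCAM_RA and 1.91 ± 0.692% in OKT3_MAdCAM_RA_TGFb (SD, exact permutation tests below). MALAT1, a noncoding RNA of the nucleus, took 1.74 ± 0.449%, 0.165 ± 0.141% and 0.279 ± 0.143%. The number of genes with a count was 17260.5 ± 288 in OKT3, 15293 ± 478 in OKT3_MAdCAM_RA and 15989 ± 375 in OKT3_MAdCAM_RA_TGFb. All 3 measures separated OKT3 from each other group without overlap (exact permutation p = 0.00794, the smallest this design allows, 0.0159 after adjustment over 12 tests). Between OKT3_MAdCAM_RA_TGFb and OKT3_MAdCAM_RA the exact p was 0.0397 for genes with a count (0.068 adjusted), 0.571 for RNR2 and 0.23 for MALAT1. The number of genes with a count was higher with TGF-beta in each of the 5 donor pairs. The order of the groups was the same within sequencing runs: the RNR2 share was 4.96, 1.85 and 2.22% in run 2 and 4.94, 2.04 and 2.17% in run 3. The MALAT1 share was 1.36, 0.136 and 0.310% in run 2 and 2.12, 0.407 and 0.441% in run 3. Genes with a count numbered 17254, 15423 and 16140 in run 2 and 17267, 15958 and 16293 in run 3. Run 3 held 2 OKT3 libraries and 1 library of each other group, and run 4 held no OKT3 library. RNR1, the small mitochondrial ribosomal RNA, did not follow RNR2. It took 0.0703 ± 0.0148% of counts in OKT3, 0.0879 ± 0.0240% in OKT3_MAdCAM_RA and 0.0850 ± 0.0282% in OKT3_MAdCAM_RA_TGFb (SD, not tested).

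**Figure D1:**
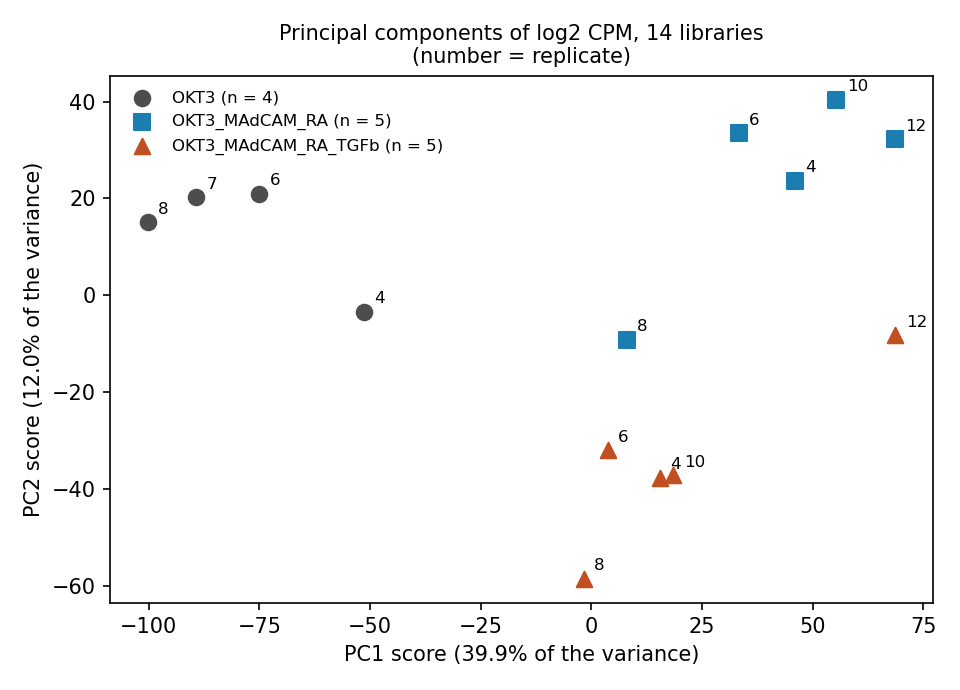
Scores of the 14 libraries on the first 2 principal components of log2 CPM, which hold 39.9% and 12.02% of the variance; each point is a library and its number the replicate. The first component separated OKT3 (4 libraries) from the other groups, and OKT3_MAdCAM_RA replicate 8 and OKT3_MAdCAM_RA_TGFb replicate 12 lay apart from their own groups.

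Adding MAdCAM with retinoic acid to OKT3 asked how these gut-associated signals change activated CD8+ T cells. ITGAE, the αE integrin chain (CD103) that marks tissue-resident cells, rose from 26.3 ± 5.85 CPM in OKT3 (n = 4) to 102 ± 29.2 CPM in OKT3_MAdCAM_RA (n = 5), a log2 fold change of 1.96 ± 0.23 (edgeR adjusted p = 3.05e-05). KLF2, the transcription factor behind tissue exit, fell from 34.3 ± 14.2 to 3.02 ± 1.88 CPM (log2 fold change -3.50 ± 0.48, adjusted p = 7.48e-05). Its target S1PR1, the receptor for lymphatic egress, fell from 220.4 ± 108 to 53.2 ± 16.4 CPM (-2.05 ± 0.33). The mitotic kinase CDK1 rose from 77.4 ± 34.6 to 804 ± 236 CPM (3.38 ± 0.32). Each gene named for this comparison as past the threshold differed in the same direction in each of the 3 donor pairs. In all, 2541 genes were higher and 2415 lower, 1541 and 1867 of them by at least 2-fold. ITGAE (chromosome 17, 3714628 to 3801188) overlaps P2RX5, so its count is uncertain. KLF2 lies on chromosome 19 (16324826 to 16328685), S1PR1 on chromosome 1 (101236899 to 101242313) and CDK1 on chromosome 10 (60778331 to 60794852).

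Of the gene lists, cell cycle genes rose the most at this step: 54 of 60 tested members were higher (56 adjusted over the list alone), with a median log2 fold change of 2.13 (camera adjusted p = 2.39e-29). The adjusted p was 0.219 with an estimated correlation. Examples were the mitotic cyclin CCNB1 (3.89 ± 0.47), the kinase AURKB (3.49 ± 0.37) and the proliferation marker MKI67 (2.37 ± 0.40, from 2.15 to 11.2 CPM). Genes of oxidative phosphorylation were higher for 46 of 52 members (47 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 4.04e-18, adjusted p = 0.486 with an estimated correlation). Among them were the complex I subunit NDUFA9 (1.65 ± 0.24) and the ATP synthase subunit ATP5F1B (1.43 ± 0.19). Cholesterol and lipid synthesis genes had 14 higher and 1 lower of 36 (14 and 1 adjusted over the list alone, 8 and 1 with the replicate block), with a median of 0.71 (camera adjusted p = 0.00655, adjusted p = 0.486 with an estimated correlation). The sterol isomerase EBP (1.77 ± 0.29) and the fatty acid carrier FABP5 (2.41 ± 0.36) were among them. The ATF4 amino acid response had 10 higher and 1 lower of 31 (10 and 1 adjusted over the list alone), with a median of 0.45. The serine synthesis enzymes PSAT1 (1.67 ± 0.25) and PSPH (2.01 ± 0.34) were among the risers. Its camera adjusted p was 0.0234 (adjusted p = 0.486 with an estimated correlation) and 0.0662 without OKT3 replicate 8.

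Interferon response genes fell: 28 of 42 were lower (32 adjusted over the list alone, 18 with the replicate block), with a median of -1.90 (camera adjusted p = 4.48e-07, adjusted p = 0.503 with an estimated correlation). The GTPase GBP5 changed by -1.90 ± 0.40. Of 26 naive and central memory genes 19 were lower (21 adjusted over the list alone), with a median of -1.53 (camera adjusted p = 1.9e-07, adjusted p = 0.486 with an estimated correlation). IL7R, the interleukin 7 receptor, fell from 1149 ± 430.4 to 148 ± 84.8 CPM (-2.96 ± 0.44), and CCR7, a lymph node homing receptor, from 789 ± 283 to 269 ± 126 CPM (-1.55 ± 0.33). Of 29 genes known to be lower in TRM than in circulating cells 15 were lower (17 adjusted over the list alone), with a median of -1.48 (camera adjusted p = 4.58e-06, adjusted p = 0.219 with an estimated correlation, 0.0131 with that and the replicate block). KLF3 (-1.96 ± 0.31) and RASGRP2 (-3.22 ± 0.52) were among them, beside KLF2, S1PR1 and CCR7. The medians of the 7 lists past the threshold kept their sign within the 2 runs that hold both groups: 1.46 and 2.96 for cell cycle, 1.08 and 0.66 for oxidative phosphorylation, 0.31 and 0.56 for cholesterol, and 0.14 and 1.02 for ATF4. For the falling lists they were -1.30 and -1.29 for interferon, -1.33 and -1.15 for naive genes, and -1.24 and -1.47 for TRM-lower genes. Run 2 held 2 libraries of each group, while run 3 held 1 of OKT3_MAdCAM_RA and 2 of OKT3. Of all genes called, 99.8% in run 2 and 98.8% in run 3 differed in the called direction, against 81.1 and 71.8% of the other genes. The genes were called on these same libraries, so such agreement is largely set in advance and is no separate support.

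The list of genes higher in TRM did not move one way: 4 of 27 were higher and 6 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.923). ITGAE rose, while RUNX3, a transcription factor of CD8 residency, fell by 1.19 on the log2 scale (SE 0.39, adjusted p = 0.0254). That call was lost without OKT3 replicate 4 or 8 or OKT3_MAdCAM_RA replicate 6, 10 or 12 (adjusted p = 0.0537 to 0.0795), and RUNX3 overlaps RUNX3-AS1. The retinoic acid response list had 1 higher and 4 lower of 16 (1 and 4 adjusted over the list alone, 3 and 3 with the replicate block, camera adjusted p = 0.181). The corepressor NRIP1 changed by -1.27 ± 0.26 and the receptor RARA by -2.02 ± 0.59 (adjusted p = 0.0134, 0.0852 with the replicate block, overlapping RARA-AS1). Genes of the TGF-beta response had 1 higher and 8 lower of 32 (1 and 8 adjusted over the list alone, camera adjusted p = 0.17). The receptor chain TGFBR2 stood at -1.80 ± 0.33, the feedback regulator SKIL at -1.57 ± 0.29 and PMEPA1 at -2.14 ± 0.61. PMEPA1 was low in both groups, at 0.830 to 2.66 CPM in OKT3 and 0 to 0.758 CPM in OKT3_MAdCAM_RA. Its call was lost under 1 alternative (highest adjusted p over all alternatives 0.0734). Gut homing genes had 1 higher and 9 lower of 22 (1 and 11 adjusted over the list alone, camera adjusted p = 0.0507, 0.0104 with the replicate block). The adjusted p was 0.503 with an estimated correlation and 0.156 with that and the block. The gut homing list passed without OKT3 replicate 4, 6 or 7, OKT3_MAdCAM_RA replicate 8, or OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 8 (adjusted p = 0.0141 to 0.0499). The gut chemokine receptor CCR9 stood at 28.5 ± 19.9 CPM in OKT3 and 53.6 ± 20.2 CPM in OKT3_MAdCAM_RA (0.91 ± 0.43, adjusted p = 0.107). It passed with the replicate block (1.40, adjusted p = 0.0168) and without OKT3 replicate 8 (1.44, adjusted p = 0.0205). CCR9 overlaps LZTFL1. Over all alternatives the adjusted p ran from 0.00477 to 0.0852 for RARA, 0.0124 to 0.245 for CCR9 and 0.00706 to 0.503 for the gut homing list.

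Cytotoxic effector genes moved both ways, 5 higher and 7 lower of 35 (5 and 7 adjusted over the list alone, 4 and 13 with the replicate block, camera adjusted p = 0.5). Granzyme B, GZMB, rose from 338 ± 237 to 2755 ± 2566 CPM (3.03 ± 0.82, adjusted p = 0.00879), a call lost with the replicate block (1.96, adjusted p = 0.0561, 0.000797 to 0.142 over all alternatives). Perforin, PRF1, stood at -0.86 ± 0.31 (adjusted p = 0.0352), and its call was lost without OKT3 replicate 4 or 8 or OKT3_MAdCAM_RA replicate 6, 10 or 12 (adjusted p = 0.0608 to 0.152). The glycolytic enzymes GAPDH (2.06 ± 0.22) and PGK1 (1.42 ± 0.17) rose, in a list with 7 higher and 5 lower of 31 (camera adjusted p = 0.147, 0.0279 without OKT3 replicate 4). Of 20 T and CD8 identity genes 1 was higher and 6 lower (camera adjusted p = 0.0813, 0.0493 without OKT3_MAdCAM_RA replicate 4), among them CD247 (-1.16 ± 0.19) and BCL11B (-1.83 ± 0.37). Of 10 nuclear noncoding RNAs 3 were lower (camera adjusted p = 0.187, 0.0275 with the replicate block), MALAT1 among them (-3.20 ± 0.52, overlapping TALAM1). Of 11 NK cell markers 4 were lower (camera adjusted p = 0.109, 0.0275 with the replicate block). Over all alternatives these ran from 0.00107 to 0.486 for the nuclear RNAs and 0.000432 to 0.486 for the NK markers. The remaining lists did not pass, with higher and lower counts of 8 and 5 of 46 for T cell activation (camera adjusted p = 0.545), 3 and 5 of 33 for inhibitory receptors and exhaustion (0.5, 3 and 8 with the block), 7 and 8 of 36 for cytokines and chemokines (0.806, 4 and 5 with the block), and 4 and 3 of 13 for type 2 genes (0.938). These counts were 3 and 1 of 14 for regulatory T cell genes (0.923), 6 and 4 of 19 for heat shock genes (0.187) and 7 and 6 of 25 for apoptosis (0.923). Type 17 genes had 3 lower of 15 (0.418), CD4 T cell markers 3 higher of 7 (0.858) and B cell markers 1 lower of 5 (0.861). For the 9 innate-like T cell markers (camera adjusted p = 0.408) edgeR gave 0 calls, with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by limma voom. Median and mean log2 fold change differed in sign for cytokines (-0.28 and 0.14), type 2 genes (-0.20 and 0.34) and B cell markers (0.18 and -0.52).

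Outside the lists, the largest changes at this step included rises of SLC26A4, an anion exchanger (6.91 ± 1.42, overlapping SLC26A4-AS1), and HSD11B1, which regenerates cortisol (4.73 ± 0.95, overlapping HSD11B1-AS1). DKK3 fell from 11.2 ± 6.67 to 0.337 ± 0.506 CPM (-5.00 ± 0.81). The desmosomal cadherin DSC1 had no count in OKT3_MAdCAM_RA and was at least 67.2-fold lower there, with the floor of 3 counts taken over the group. The comparison moved with the RNR2 and MALAT1 shares and the number of genes with a count, as given above.

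**Figure D2:**
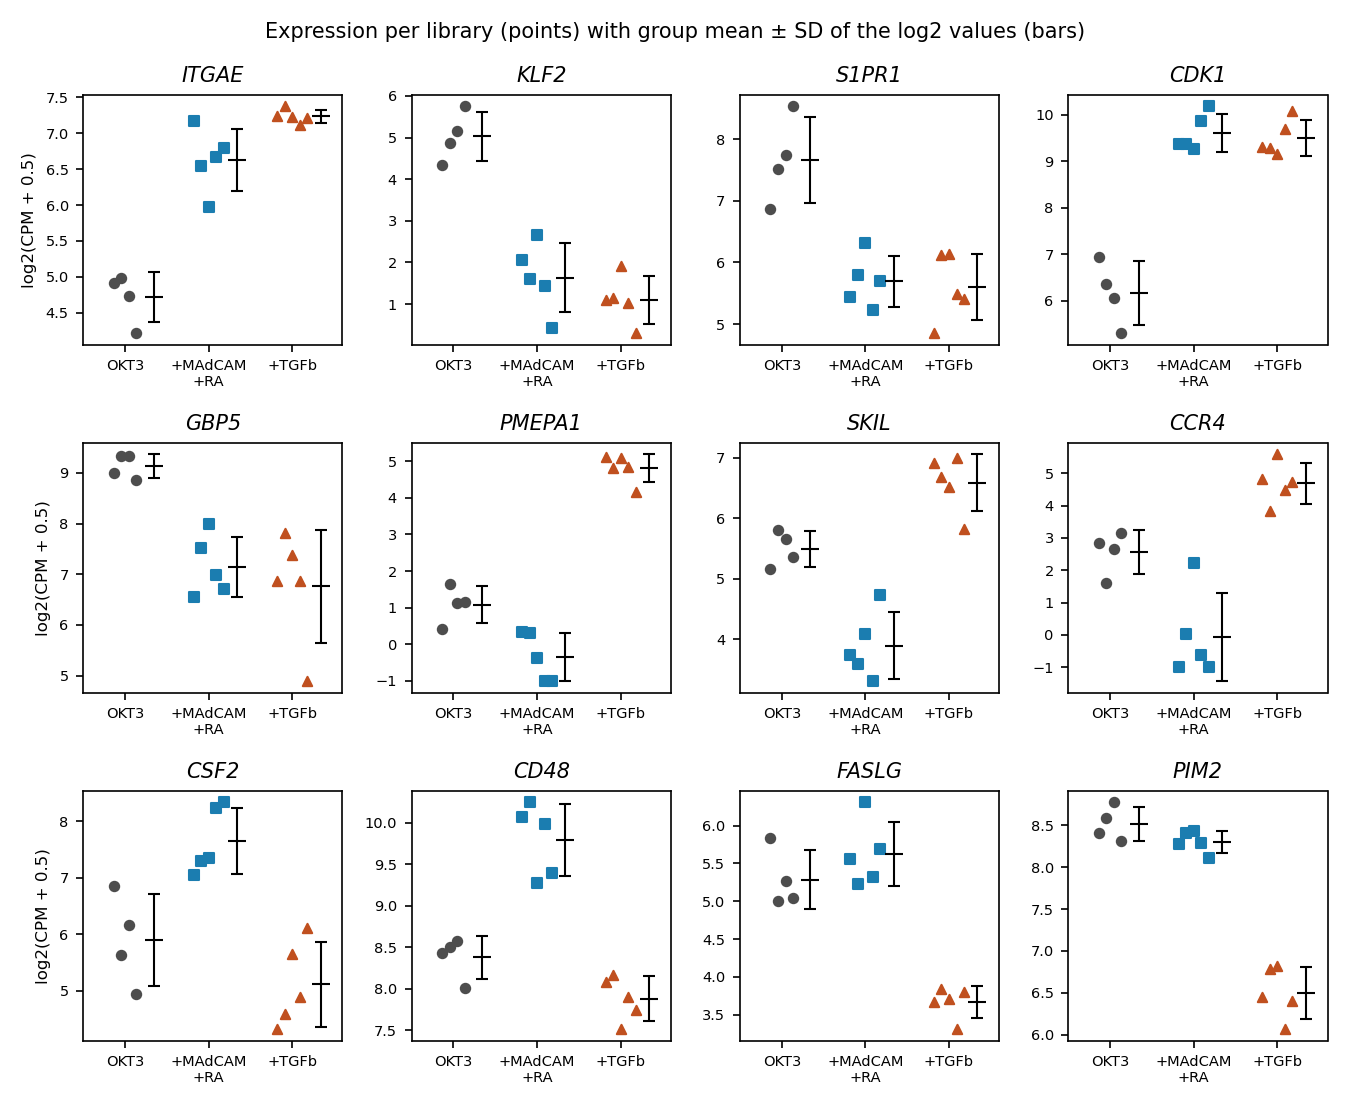
log2 CPM (offset 0.5) of 12 genes in each library (points) with the group mean ± SD (bars), for OKT3 (n = 4), OKT3_MAdCAM_RA (n = 5) and OKT3_MAdCAM_RA_TGFb (n = 5). PMEPA1 and SKIL fell at the first step and rose with TGF-beta, while KLF2 and S1PR1 stayed low in both groups with MAdCAM and retinoic acid. The fall of PMEPA1 lay between low values, 0.830 to 2.66 CPM in OKT3 and 0 to 0.758 CPM in OKT3_MAdCAM_RA.

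Adding TGF-beta to MAdCAM with retinoic acid asked what this cytokine, known to drive TRM formation, contributes on top. PMEPA1, a feedback inhibitor of TGF-beta signalling, rose from 0.353 ± 0.376 CPM (n = 5) to 28.2 ± 6.69 CPM (n = 5), a log2 fold change of 6.18 ± 0.60 (edgeR adjusted p = 1.88e-05). SKIL, another, rose from 15.3 ± 6.61 to 99.5 ± 28.2 CPM (2.71 ± 0.29). The chemokine receptor CCR4, linked to skin and type 2 homing, rose from 0.979 ± 1.83 to 27.3 ± 12.5 CPM (4.79 ± 0.84, adjusted p = 0.00698). The inflammatory cytokine CSF2 (GM-CSF) fell from 214 ± 88.8 to 38.0 ± 20.5 CPM (-2.50 ± 0.40, adjusted p = 0.0041). The death ligand FASLG fell from 50.6 ± 16.7 to 12.3 ± 1.74 CPM (-2.04 ± 0.25) and the adhesion protein CD48 from 918 ± 260.4 to 239 ± 42.8 CPM (-1.94 ± 0.21). Each gene named for this comparison as past the threshold differed in the same direction in each of the 5 donor pairs. In all, 163 genes were higher and 90 lower (423 and 426 with the replicate block, which called 252 of the 253 again), 139 and 40 of them by at least 2-fold. Without OKT3_MAdCAM_RA replicate 8 and OKT3_MAdCAM_RA_TGFb replicate 12, the libraries that lay apart from their groups, the counts were 1046 and 1005. Without OKT3_MAdCAM_RA replicate 8 alone they were 430 and 340, and without OKT3_MAdCAM_RA_TGFb replicate 12 alone 400 and 494. The higher count was 74 to 107 without OKT3_MAdCAM_RA_TGFb replicate 4, 6, 8 or 10 or OKT3_MAdCAM_RA replicate 6, 10 or 12. The lower count was 20 to 59 without any of these, OKT3_MAdCAM_RA replicate 4 or OKT3 replicate 6 or 7. PMEPA1 (chromosome 20, 57648396 to 57711472) overlaps NKILA, CCR4 lies on chromosome 3 (32951644 to 32956349), CSF2 on chromosome 5 (132073789 to 132076170), and FASLG (172659103 to 172666876) and CD48 (160678746 to 160711822) on chromosome 1.

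The TGF-beta response list rose: 6 of 32 members were higher (14 higher and 3 lower adjusted over the list alone, 7 and 2 with the replicate block), with a median log2 fold change of 0.67 (camera adjusted p = 3.82e-07). With an estimated correlation it stayed past the threshold (adjusted p = 0.0337), but not with that and the replicate block (0.0889). Its risers included LDLRAD4, which restrains TGF-beta receptors, from 22.2 ± 4.74 to 117 ± 13.1 CPM (2.40 ± 0.22). Others were the TGF-beta-induced repressor KLF10 (1.60 ± 0.32) and CD101, an inhibitory receptor of resident T cells (3.16 ± 0.73, adjusted p = 0.0335). The CD101 call was lost without OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 8 or OKT3_MAdCAM_RA replicate 6, 10 or 12 (adjusted p = 0.0714 to 0.105). Of 27 genes known to be higher in TRM 5 were higher and 1 lower (7 and 2 adjusted over the list alone, 7 and 2 with the replicate block), with a median of 0.62 (camera adjusted p = 0.00973, adjusted p = 0.284 with an estimated correlation). That call was lost without OKT3_MAdCAM_RA_TGFb replicate 8 (adjusted p = 0.0722) or 10 (adjusted p = 0.0543). The transcription factor AHR rose by 1.73 ± 0.31 and the actin-capping protein CAPG by 1.76 ± 0.35 (both overlap another gene), and the keratin KRT86, without a count in OKT3_MAdCAM_RA, was at least 20.1-fold higher (overlapping KRT81). Each of these calls was lost under 1 alternative, with a highest adjusted p over all alternatives of 0.0596 for AHR, 0.0947 for CAPG and 0.0981 for KRT86. KRT86 was tested in 20 alternatives only. The lower member was PRDM1, which encodes BLIMP1, from 46.6 ± 19.0 to 15.1 ± 7.57 CPM (-1.63 ± 0.35, adjusted p = 0.0258). Its call was lost without OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 10 or OKT3_MAdCAM_RA replicate 10 or 12 (adjusted p = 0.0594 to 0.075).

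Cytotoxic effector genes fell as a list with TGF-beta: 4 of 35 were lower (4 adjusted over the list alone, 10 with the replicate block), with a median of -0.32 (camera adjusted p = 0.000183, adjusted p = 0.284 with an estimated correlation, 0.0120 with that and the replicate block). Beside FASLG, interferon gamma, IFNG, fell from 1151 ± 442 to 327 ± 199 CPM (-1.81 ± 0.42, adjusted p = 0.0335). The IFNG call was lost without OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 8 or OKT3_MAdCAM_RA replicate 10 or 12 (adjusted p = 0.0724 to 0.0987). Granzyme A, GZMA, stood at -0.74 ± 0.57 (adjusted p = 0.556) and passed with the replicate block (-0.96, adjusted p = 0.00577, 0.00577 to 0.839 over all alternatives). Cytokines and chemokines had 4 lower of 36 (1 higher and 7 lower adjusted over the list alone, 3 and 4 with the replicate block), with a median of -0.33 (camera adjusted p = 0.0421, 0.0795 with the replicate block, adjusted p = 0.284 with an estimated correlation). Their call was also lost without OKT3_MAdCAM_RA_TGFb replicate 4 or 12 or OKT3_MAdCAM_RA replicate 6, 8 or 12 (adjusted p = 0.0589 to 0.137), and ran from 0.00514 to 0.284 over all alternatives. Oxidative phosphorylation genes had 1 lower of 52 (1 adjusted over the list alone, 6 with the replicate block), with a median of -0.30 (camera adjusted p = 3.82e-07, adjusted p = 0.75 with an estimated correlation). The cell cycle list had a median of 0.27 (camera adjusted p = 0.0277, 0.0613 with the replicate block, adjusted p = 0.91 with an estimated correlation). It was lost without OKT3_MAdCAM_RA replicate 4 or 6 or OKT3_MAdCAM_RA_TGFb replicate 10 or 12 (adjusted p = 0.0564 to 0.185). Of its 60 genes edgeR called 0, with 5 at an unadjusted p under 0.05, 1 by DESeq2 and 3 by limma voom. Within runs 2, 3 and 4 the medians were 0.53, 0.65 and 0.52 for the TGF-beta response, 0.57, 0.43 and 0.56 for TRM-higher genes, and -0.54, -0.42 and -0.54 for cytotoxic genes. They were -0.29, -0.09 and -0.35 for cytokines, -0.53, 0.03 and -0.24 for oxidative phosphorylation, whose sign turned in run 3, and 0.22, 0.32 and 0.34 for cell cycle. Runs 2 and 4 held 2 libraries of each group, but run 3 held only 1 of each, so its values have no replicate. Its OKT3_MAdCAM_RA library was replicate 8, which lay apart from its group. Of the genes called, 100, 99.2 and 100% differed in the called direction within the runs, against 81.5, 68.3 and 80.3% of the others. As at the first step, they were called on the same libraries, so this is no separate support.

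Homing receptors moved in part. Gut homing genes had 3 higher of 22 (5 higher and 1 lower adjusted over the list alone), among them CXCR3, a receptor for interferon-induced chemokines (2.02 ± 0.26). CCR4, linked above to skin and type 2 homing, was another, so the risers of this list were not all gut receptors. The list's camera adjusted p was 0.0621, with 0.0342 without OKT3 replicate 8 and 0.00713 without OKT3_MAdCAM_RA replicate 8. It was 0.75 with an estimated correlation, 0.305 with that and the replicate block, and up to 0.242 without other single libraries. ITGAE stood at 102 ± 29.2 CPM without and 150.3 ± 9.87 CPM with TGF-beta (0.56 ± 0.20, adjusted p = 0.156, 0.0598 with the replicate block) and was higher in each of the 5 donor pairs. It passed with limma voom (0.61, adjusted p = 0.0328, with 0.0328 to 0.284 over all alternatives). Both CXCR6, a TRM chemokine receptor (-1.33 ± 0.34, adjusted p = 0.0541), and CCR7 (0.98 ± 0.31, adjusted p = 0.111) missed the threshold and passed it with the replicate block (-1.40, adjusted p = 0.00153, and 1.08, adjusted p = 0.00219). CXCR6 also passed without OKT3_MAdCAM_RA replicate 4 or OKT3_MAdCAM_RA_TGFb replicate 10 or 12 (adjusted p = 0.0401 to 0.0469). Over all alternatives the adjusted p ran from 0.00153 to 0.129 for CXCR6, 0.00219 to 0.257 for CCR7 and 0.0446 to 0.487 for ITGB7. The integrin chain ITGB7, the partner of both αE and α4 (overlapping ZNF740), stood at -0.50 ± 0.24 (adjusted p = 0.301) and passed with the replicate block (-0.53, adjusted p = 0.0446).

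T cell activation genes had 3 higher and 2 lower of 46 (9 and 7 with the replicate block, camera adjusted p = 0.621). The cytokine receptor chain IL2RB (1.88 ± 0.36) and CD83 (1.33 ± 0.22) rose. The survival gene BCL2A1 (-1.23 ± 0.22) and TNFSF8, the CD30 ligand (-1.43 ± 0.30), fell. The calls of BCL2A1 and TNFSF8 were each lost under 1 alternative (highest adjusted p over all alternatives 0.0559 and 0.0536). Of 16 retinoic acid response genes 1 was higher, NRIP1 (1.63 ± 0.25, camera adjusted p = 0.757), and of 36 cholesterol genes 1, SQLE (1.22 ± 0.21, camera adjusted p = 0.442). Of the other lists, inhibitory receptors and exhaustion had 2 higher and 1 lower of 33 (camera adjusted p = 0.701, 5 and 4 with the block), naive genes 1 lower of 26 (0.621, 3 higher and 1 lower with the block), glycolysis and hypoxia 2 lower of 31 (0.542), and the ATF4 response 1 higher of 31 (0.264). There was 1 higher of 15 for type 17 genes (0.818), 1 of 13 for type 2 genes (0.207), 2 of 19 for heat shock genes (0.972) and 1 of 11 for NK cell markers, CLIC3 of the chloride channel family (4.45 ± 0.43, camera adjusted p = 0.115, and 0.0284 without OKT3_MAdCAM_RA_TGFb replicate 6). The camera direction of type 17 genes was up although their median was -0.36, and heat shock genes had a median of -0.14 and a mean of 0.18. In 10 lists, with 220 genes together, edgeR gave 0 calls, with 33 at an unadjusted p under 0.05, 9 by DESeq2 and 10 by limma voom. Among these, besides cell cycle, the interferon response had a camera adjusted p of 0.0621 (median -0.55) and passed with the replicate block (0.00728, 1 higher and 7 lower). It also passed without OKT3 replicate 4 or 7, OKT3_MAdCAM_RA replicate 4, 10 or 12, or OKT3_MAdCAM_RA_TGFb replicate 6 or 8 (adjusted p = 0.0005 to 0.0484), with 0.91 with an estimated correlation as the highest of all alternatives. The camera adjusted p of the other 8 was 0.972 for TRM-lower genes, 0.757 for regulatory T cell genes, 0.175 for CD4 T cell markers, and 0.972 for B cell markers. It was 0.607 for innate-like T cell markers, 0.338 for T and CD8 identity, 0.276 for nuclear noncoding RNAs and 0.972 for apoptosis. Outside the lists, the largest changes included INAVA, a regulator of epithelial junctions and innate signalling, which had no count in OKT3_MAdCAM_RA and was at least 82.0-fold higher with TGF-beta. The interleukin 1 receptor antagonist IL1RN (5.87 ± 0.86), the protease CTSL (5.57 ± 0.90), DKK3 (4.75 ± 0.79) and DIXDC1 (4.66 ± 0.46) rose. The kinase PIM2 (-1.78 ± 0.16) and the lysosomal channel MCOLN2 (-1.70 ± 0.23) fell.

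**Figure D3:**
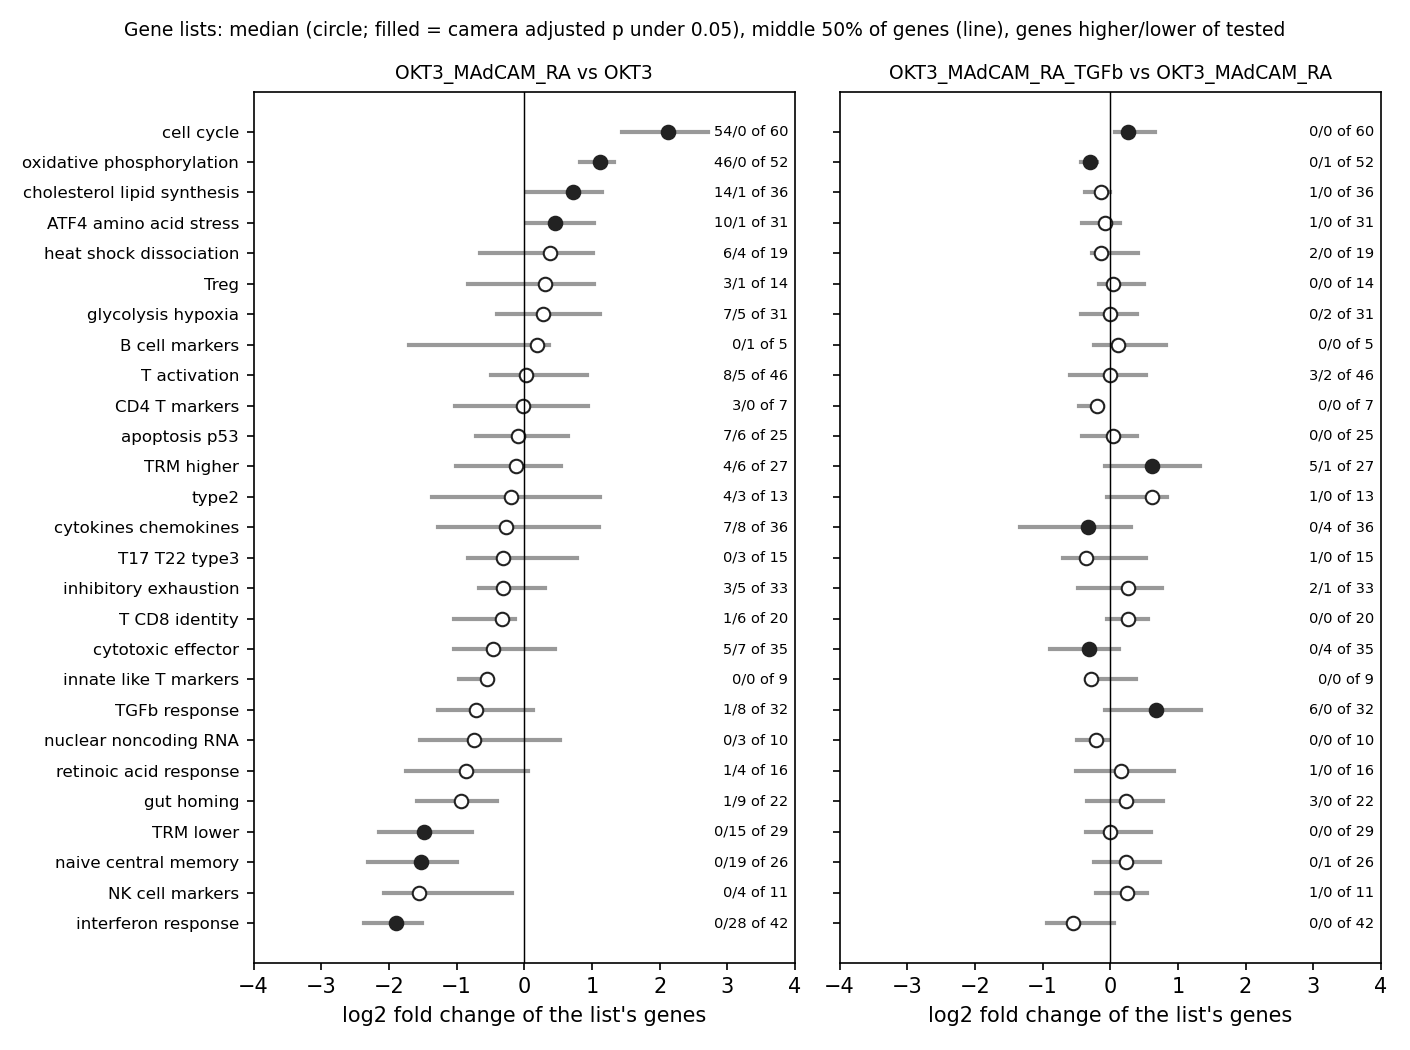
Median log2 fold change of each of the 27 lists tested (circles, filled where the camera adjusted p was under 0.05), with the range of the middle 50% of its genes (lines) and the genes higher and lower of those tested, for both steps. Cell cycle (54 of 60 higher) and interferon response genes (28 of 42 lower) stood at the ends of the first step, and the TGF-beta response (median 0.67) led the second.

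The full combination against OKT3 asked what all signals together do. ITGAE rose from 26.3 ± 5.85 (n = 4) to 150.3 ± 9.87 CPM (n = 5), a log2 fold change of 2.52 ± 0.23 (edgeR adjusted p = 7.76e-06). KLF2 fell from 34.3 ± 14.2 to 1.78 ± 0.914 CPM (-4.27 ± 0.50, adjusted p = 4.86e-05). S1PR1 (-2.12 ± 0.33) also fell. The TGF-beta feedback genes PMEPA1 (4.04 ± 0.56), LDLRAD4 (2.54 ± 0.25) and SKIL (1.14 ± 0.29) ended above OKT3. Granulysin, GNLY, a cytolytic granule protein, fell from 125 ± 74.8 to 15.1 ± 9.41 CPM (-3.05 ± 0.60), and CD8A, a chain of the CD8 coreceptor, from 635 ± 142 to 386 ± 50.9 CPM (-0.72 ± 0.17, adjusted p = 0.00434). The CD8A call was lost under 1 alternative (highest adjusted p over all alternatives 0.0653). In all, 2106 genes were higher and 1564 lower, 1191 and 1157 of them by at least 2-fold. Without OKT3 replicate 7 the lower count was 1036. Except for GPR15 below, each gene named for this comparison as past the threshold differed in the same direction in each of the 3 donor pairs. The comparison moved with the RNR2 and MALAT1 shares and the number of genes with a count.

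Cell cycle genes were higher for 58 of 60 (59 adjusted over the list alone), with a median of 2.53 (camera adjusted p = 7.6e-46, adjusted p = 0.0974 with an estimated correlation). CDK1 (3.27 ± 0.32), NUSAP1 (3.28 ± 0.30) and MKI67 (2.62 ± 0.40) were among them. Oxidative phosphorylation genes were higher for 37 of 52 (42 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 6.84e-12, adjusted p = 0.457 with an estimated correlation). UQCRC1 (1.36 ± 0.21) and ATP5F1B (1.06 ± 0.19) were among them. Cholesterol and lipid synthesis had 11 higher and 1 lower of 36 (12 and 2 adjusted over the list alone, 8 and 2 with the replicate block), with a median of 0.64 (camera adjusted p = 0.0123, adjusted p = 0.457 with an estimated correlation), SQLE among them (1.59 ± 0.23). Interferon response genes were lower for 37 of 42 (41 adjusted over the list alone, 22 with the replicate block), with a median of -2.28 (camera adjusted p = 1.49e-12, adjusted p = 0.457 with an estimated correlation). GBP5 (-2.11 ± 0.41) and IFITM1 (-2.53 ± 0.40) were among them. TRM-lower genes were lower for 16 of 29 (16 adjusted over the list alone), with a median of -1.35 (camera adjusted p = 1.62e-07, adjusted p = 0.131 with an estimated correlation, 0.00434 with that and the replicate block). Naive and central memory genes were lower for 16 of 26 (17 adjusted over the list alone), with a median of -1.44 (camera adjusted p = 1.56e-08, adjusted p = 0.383 with an estimated correlation), IL7R among them (-2.69 ± 0.43).

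Cytotoxic effector genes had 2 higher and 14 lower of 35 (3 and 15 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.00162, adjusted p = 0.383 with an estimated correlation, 0.00434 with that and the replicate block). Besides GNLY, the fractalkine receptor CX3CR1 (-2.35 ± 0.49), FASLG (-1.69 ± 0.26), PRF1 (-1.18 ± 0.31) and IFNG (-1.45 ± 0.43, adjusted p = 0.0184, and 0.0822 without OKT3 replicate 4) fell. Of 10 nuclear noncoding RNAs 3 were lower (4 adjusted over the list alone), with a median of -0.90, MALAT1 (-2.56 ± 0.51) and NEAT1 (-2.16 ± 0.32) among them. Their camera adjusted p was 0.0191 (adjusted p = 0.133 with an estimated correlation), with 0.0566 without OKT3_MAdCAM_RA_TGFb replicate 6 and 0.0725 without RNR1, RNR2, MALAT1 and TALAM1. Within runs 2 and 3 the medians were 1.86 and 3.54 for cell cycle, 0.50 and 0.65 for oxidative phosphorylation, 0.42 and 0.57 for cholesterol, and -1.43 and -1.83 for interferon. They were -0.95 and -1.14 for TRM-lower, -0.92 and -1.20 for naive, -0.91 and -0.73 for cytotoxic genes and -1.13 and -0.84 for nuclear RNAs. Run 2 held 2 libraries of each group, while run 3 held 1 of OKT3_MAdCAM_RA_TGFb and 2 of OKT3. Of all genes called, 99.9 and 99.6% differed in the called direction within these runs, against 80.9 and 76.5% of the others. Here too the genes were called on the same libraries, so this is no separate support.

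Genes higher in TRM had 8 higher and 1 lower of 27 (8 and 1 adjusted over the list alone, 7 and 4 with the replicate block, camera adjusted p = 0.185). The adhesion protein JAML rose by 2.03 ± 0.28 and PRDM1 fell by 1.70 on the log2 scale (SE 0.37). ITGA1, the collagen-binding integrin chain CD49a (overlapping PELO), stood at 1.73 ± 0.60 (adjusted p = 0.0411, 0.0546 with the replicate block) and CD101 at 2.04 ± 0.74 (adjusted p = 0.0482). The ITGA1 call was lost without OKT3 replicate 4, 6, 7 or 8 or OKT3_MAdCAM_RA_TGFb replicate 8 or 10 (adjusted p = 0.0525 to 0.119). The CD101 call was lost without OKT3 replicate 6, 7 or 8, OKT3_MAdCAM_RA replicate 6 or OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 8 (adjusted p = 0.0539 to 0.129). TGF-beta response genes had 8 higher and 6 lower of 32 (10 and 6 adjusted over the list alone, camera adjusted p = 0.285), and retinoic acid response genes 1 higher and 3 lower of 16 (camera adjusted p = 0.185). Gut homing genes had 4 higher and 8 lower of 22 (5 and 8 adjusted over the list alone, camera adjusted p = 0.277). The gut receptor GPR15 fell from 101 ± 91.3 to 23.6 ± 16.5 CPM (-2.11 ± 0.67, adjusted p = 0.025), was lower in 2 of 3 donor pairs, and missed the threshold with the replicate block (-1.02, adjusted p = 0.0604). The GPR15 call was also lost without OKT3 replicate 7 or 8 or OKT3_MAdCAM_RA_TGFb replicate 4, 6 or 10 (adjusted p = 0.0551 to 0.104). CCR9 stood at 1.11 ± 0.44 (adjusted p = 0.0662) and passed with the replicate block (1.61, adjusted p = 0.0114), without OKT3 replicate 8 (adjusted p = 0.0159) and without OKT3_MAdCAM_RA_TGFb replicate 10 (adjusted p = 0.0391). CXCR6 stood at -0.74 ± 0.35 (adjusted p = 0.13) and passed with the replicate block (-1.01, adjusted p = 0.00841). Over all alternatives the adjusted p ran from 0.00872 to 0.12 for ITGA1, 0.00497 to 0.106 for GPR15, 0.00663 to 0.151 for CCR9 and 0.00841 to 0.289 for CXCR6.

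Granzyme genes did not pass against OKT3: GZMB stood at 2.14 ± 0.78 (adjusted p = 0.0518) and GZMA at 0.42 ± 0.61 (adjusted p = 0.641). GZMB passed without OKT3 replicate 4, OKT3_MAdCAM_RA replicate 4, 6 or 12 or OKT3_MAdCAM_RA_TGFb replicate 4 or 6 (adjusted p = 0.0288 to 0.0438). GZMA was lower with the replicate block (-1.12, adjusted p = 0.00227, 0.00227 to 0.864 over all alternatives). T cell activation genes had 8 higher and 7 lower of 46 (camera adjusted p = 0.647), with the transcription factor IRF8 at 2.47 ± 0.46 and TNFSF8 at -2.26 ± 0.31. The T and CD8 identity list had 1 higher and 6 lower of 20 (camera adjusted p = 0.166). Some lists passed with the replicate block (camera adjusted p without it, then with it): the ATF4 response with 9 higher and 3 lower of 31 (0.0724, 0.0056 with the block) and cytokines and chemokines with 3 and 10 of 36 (0.102, 0.0495 with the block). So did heat shock genes with 7 and 4 of 19 (0.107, 0.0469 with the block) and innate-like T cell markers with 2 lower of 9 (0.158, 0.0056 with the block). With the block and an estimated correlation these 4 lists stood at 0.414, 0.395, 0.395 and 0.117. Over all alternatives their adjusted p ran from 0.00429 to 0.542, 0.00878 to 0.383, 0.00303 to 0.383 and 0.0056 to 0.593. Single libraries moved 5 lists past the threshold: ATF4 without OKT3 replicate 4 (adjusted p = 0.00429) or OKT3_MAdCAM_RA_TGFb replicate 12 (0.0364), heat shock genes without OKT3 replicate 4 (0.0445), and cytokines without OKT3 replicate 8 (0.0162). So did innate-like markers without OKT3_MAdCAM_RA_TGFb replicate 10 (0.0385), and glycolysis (8 higher and 6 lower of 31, 0.193) without OKT3 replicate 4 (0.0416). The remaining lists did not pass, with 4 higher and 7 lower of 33 for inhibitory receptors (0.578), 1 and 1 of 15 for type 17 (0.406) and 1 and 2 of 14 for regulatory T cell genes (0.647). There were 1 and 2 of 7 for CD4 T cell markers (0.642), 1 and 2 of 11 for NK cell markers (0.414) and 4 and 4 of 25 for apoptosis genes (0.838), and 4 higher of 13 for type 2 genes (0.414). For the 5 B cell markers (0.669) edgeR gave 0 calls, with 2 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by limma voom. Outside the lists, INAVA was at least 75.1-fold higher than in OKT3, where it had no count, and the noncoding RNA LINC00861 fell from 257 ± 49.7 to 15.7 ± 6.76 CPM (-4.04 ± 0.35). Of the 28 chosen genes that were tested, 3 were higher and 9 lower at the first step, 3 and 2 at the TGF-beta step, and 6 and 8 in the full combination against OKT3.

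The genes called at both steps were compared for their direction at each step. Of these, 127 moved in opposite directions, 76 falling and then rising and 51 rising and then falling, and 10 moved the same way (6 up, 4 down). Both steps share the OKT3_MAdCAM_RA libraries, so their errors oppose each other. Independent lists of these sizes would share 30.2 and 17.6 genes in the opposite ways and 31.8 and 16.7 in the same way. With the shared libraries split into separate sets for each step, a median over 20 splits of 14.5 genes fell then rose and 10 rose then fell, while 3 rose and 1 fell in both. For independent lists of those sizes the medians were 6.09, 3.30, 7.90 and 2.49. Over the splits the observed numbers ranged, in the same order, from 3 to 57, 2 to 79, 0 to 43 and 0 to 15. Over all genes tested, the log2 fold changes of both steps correlated at -0.447. In 30 simulations of unchanged groups with shared libraries the mean correlation was -0.469 (range -0.489 to -0.446), so the correlation alone shows no reversal by TGF-beta. The covariance was -0.443, against -0.147 simulated (range -0.158 to -0.135). With the shared libraries split, the medians were -0.221 for the correlation and -0.325 for the covariance. Of the 76 genes that fell and rose, 63 did not pass against OKT3 with all signals, 9 ended above and 4 below. Of the 51 that rose and fell, 39 did not pass and 12 ended above OKT3. PMEPA1 and SKIL fell and then rose, and CSF2 rose and then fell. The first-step calls of PMEPA1, at low values, and of CSF2 were each lost under 1 alternative (highest adjusted p over all alternatives 0.0734 and 0.0608). Chosen after their values were seen, ATP1B1, CD9, DHRS2, DUSP4, JAML and LOC107986072 were the genes that rose at both steps, and DNAJB9, PLEK, PRKCQ-AS1 and TNFSF8 those that fell. The opposite count was 562 without OKT3_MAdCAM_RA replicate 8 and 646 without OKT3_MAdCAM_RA_TGFb replicate 12. It was 48 to 84 without OKT3 replicate 7, OKT3_MAdCAM_RA replicate 4, 6, 10 or 12 or OKT3_MAdCAM_RA_TGFb replicate 4, 6, 8 or 10. The same-direction count was 16 without OKT3 replicate 4, 18 without OKT3_MAdCAM_RA_TGFb replicate 12, and 3 to 6 without OKT3 replicate 7 or 8, OKT3_MAdCAM_RA replicate 4, 10 or 12 or OKT3_MAdCAM_RA_TGFb replicate 4, 8 or 10. With the replicate block the counts were 478 and 22.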

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

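The tests of the background over the RNR2 and MALAT1 shares, of donors and of contaminating cells for the interferon genes, and of both explanations for the displaced libraries were chosen after the result was seen. One library lay far from the others of its group in 12 of 240 groups of values tested (Dixon's test), where chance gives about 1 in 20 (12 groups). Of these 12, OKT3_MAdCAM_RA_TGFb replicate 12 held 6. It had 15346 genes with a count (other libraries of its group 16024 to 16293), an RNR2 share of 0.670% (2.17 to 2.27%), MALAT1 at 519.8 CPM (2853 to 4084), KLF10 at 58.7 CPM (122 to 137), ATP5F1B at 3269.8 CPM (1756 to 1911) and UQCRC1 at 626 CPM (312 to 379). OKT3_MAdCAM_RA replicate 8 had ATP5F1B at 2062 CPM (2795 to 3086) and IL2RB at 88.8 CPM (32.3 to 40.4). OKT3_MAdCAM_RA_TGFb replicate 10 had CCR9 at 28.8 CPM (60.8 to 79.9). Among OKT3 libraries, AURKB stood at 1.72 CPM in replicate 8 (7.38 to 8.57), SLC26A4 at 0.531 CPM in replicate 6 (listed at 0 in the others) and SQLE at 56.8 CPM in replicate 7 (74.9 to 79.1).

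The OKT3 libraries held more genes with a count and larger RNR2 and MALAT1 shares than the OKT3_MAdCAM_RA libraries. Depth does not account for the first, since after thinning every library to the smallest total the OKT3 mean stayed 1145.25 genes above the highest OKT3_MAdCAM_RA library. A uniform background of DNA or unspliced RNA may contribute to it: gene families silent in blood cells had 2.79 times the CPM in OKT3 (1.92 times without the top gene, OR4D1), so this stays open. A uniform background read from these families cannot carry the shares. Its difference amounted to 0.0901% of counts, against an excess of 4.85% for RNR2 and MALAT1, both without the removed symbols. Silent genes make no unspliced RNA, so the families cannot show more unspliced RNA of expressed genes, and for the shares that stays open. RNR1, RNR2, MALAT1 and TALAM1 did not make the calls through scaling, as 99.9% of the called genes were called again without them. TMM trims genes with extreme ratios, so leaving these out could change little, and a wider shift of RNA content was not tested this way. A change of the cells' RNA with the treatment remains as an untested hypothesis.

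Interferon response genes were lower in OKT3_MAdCAM_RA than in OKT3. Different donors in the groups do not account for all of it: over the 3 donors with all treatments the mean of the list's median log2 difference was -0.94 (SD 0.709, range -1.74 to -0.40). The rule asked only for a mean below 0 by more than 1 SD, which is no significance test. In run 2, where both groups hold the same 2 donors, both among these 3, the median was -1.30. The blocked fit called 18 of 42 genes against 28, so a part from donors is not excluded. The 4 tested monocyte and dendritic cell markers fell within donors by about as much (-1.04, SD 0.188, a difference of -0.10, SD 0.653), as fewer monocytes would predict, and the 5 B cell markers by 0.18 (SD 0.755). Their levels are too low for such cells, which selection of CD8+ cells should remove, to carry the fall with their own transcripts. All markers of both kinds summed to 205.5 CPM in OKT3 (JCHAIN 144, LYZ 13.5, S100A8 0.0303), or 2.54% of the fall of 8085 CPM in the interferon list. That share covers only transcripts of such cells themselves, and an action of few such cells on the T cells was not tested. What stays open is that action, a part from donors and an effect of the treatment, the difference that the design names. The treatment effect is a hypothesis found and tested on the same data.

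The TGF-beta step called fewer genes with OKT3_MAdCAM_RA replicate 8 and OKT3_MAdCAM_RA_TGFb replicate 12 in the fit than without them. Exchanged treatment labels are excluded, since 0 of these 2 libraries lay on the other group's side of the TGF-beta response list. A shift of the donor shared by its libraries of both treatments is a candidate explanation. Both libraries of each of these donors deviated together (correlations 0.345 and 0.414), against a median of 0.166 and a maximum of 0.248 for the 9 other same-donor pairs. Among those 9, the OKT3 library of donor 8 correlated with the other libraries of its donor at 0.192 and 0.157. Whether such a shift is biological or arose in handling was not tested.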

How the results depend on the processing

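Leaving out RNR1, RNR2, MALAT1 and TALAM1 and leaving out both displaced libraries were chosen after the data were seen. The first step was the most stable: its gene counts stayed within 1.5 times 2541 and 2415 under every alternative run. At the TGF-beta step (163 higher, 90 lower) the counts were 423 and 426 with the replicate block, 342 and 329 with the run as a covariate, 420 and 354 with DESeq2, 488 and 440 with limma voom, 101 and 55 with only the 2 groups compared, and 1046 and 1005 without both displaced libraries. With the 3 complete donors the higher count was 81. They were 74 to 430 higher and 20 to 494 lower when 1 library was left out. Against OKT3 the full combination had 2440 lower genes with limma voom, 1323 higher and 1030 lower with the complete donors, and 1036 to 1644 lower when 1 library was left out. Genes called at both steps in the same and in opposite directions numbered 22 and 478 with the block, 16 and 378 with the run, 33 and 456 with DESeq2, 43 and 561 with voom, 6 and 62 with the 2 groups, 5 and 78 with the complete donors, 34 and 1603 without both displaced libraries, and 3 to 18 and 48 to 646 when 1 library was left out. Lists past the threshold (7, 6 and 8) numbered 0, 1 and 0 with an estimated correlation and 15, 3 and 16 with fry, which does not compare a list with other genes, and 11 at the first step with no filter. The cause of these changes was not tested. On the simulated counts DESeq2 made 19, 40 and 30 false calls for the 3 comparisons, against 3, 7 and 5 for the main fit. Of the 37, 34 and 36 genes named for the 3 comparisons, 30 of 36, 21 of 29 and 27 of 32 called ones passed under every alternative that tested them. Not every alternative tested each gene: the stricter filter kept 96 gene results, against 107 with the replicate block. GZMA in the full combination against OKT3 reversed from 0.42 to -1.12 with the block, -0.97 with the run and -1.25 with the complete donors. Besides those given in the text, the block changed no other call of a named gene, or of a list at the preset or an estimated correlation. RLE size factors changed no call of a named gene. In the simulated counts, where few genes were changed, a 2-fold change was found in 19.4 to 26.5% of planted genes. At the TGF-beta step, where 1.94% of genes were called, most changes of that size would thus be missed at this depth and size. At the first step and against OKT3, 38.1 and 28.2% of genes were called. The p cutoff is looser there, so the simulation does not give the share missed.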

Other observations

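The grouping of genes by the letters that begin their symbols (145 families of at least 10 tested genes) was chosen after the data were seen. Members were taken by these letters alone, without a check of function or biotype, so a family can hold genes of other kinds. At the MAdCAM and retinoic acid step, genes for proteins of the mitochondrial ribosome rose. Of 49 MRPL genes 46 were higher (median log2 fold change 1.26, camera adjusted p = 5.34e-21, 0.419 with an estimated correlation), and of 28 MRPS genes 24 (1.01, 5.69e-10, 0.419). The families with the letters of mitochondrial import genes (TIMM, 10 of 15 higher, median 1.37), chaperonin subunits (CCT, 7 of 10, 1.39) and RNA exosome subunits (EXOSC, 8 of 10, 1.36) rose as well. The family of symbols with H before a digit, the form of histone gene symbols, had 22 higher and 4 lower of 42 (1.28, adjusted p = 3.97e-05). Zinc finger genes were lower, with 139 ZNF genes lower and 11 higher of 421 (-0.98, adjusted p = 7.53e-07), as were 10 of 33 ZBTB genes (1 higher) and 6 of 12 KLF genes, the family of KLF2. With an estimated correlation the adjusted p was 0.501 for the H family and 0.419 for each of the other families given here. Against OKT3, 35 of 49 MRPL genes were higher with all signals (0.90, adjusted p = 5.37e-12, and 0.587 with an estimated correlation).

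Of the platelet and erythroid markers HBD had the highest mean, 20.01 CPM in OKT3, 2.68 CPM in OKT3_MAdCAM_RA and 2.78 CPM in OKT3_MAdCAM_RA_TGFb, and the monocyte and dendritic cell markers summed to 33.5 CPM in OKT3.

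The libraries of each pair of groups were also split in other ways, 100 splits per comparison with the real one included. These splits were drawn without regard to the donor pairs. At the first step only 1 split, the real one, gave as many as the 2541 higher and 2415 lower genes (2216 and 2067 as the highest of the others). The same held for the 2106 higher and 1564 lower genes of the full combination against OKT3 (1 as large for each, highest other 834 and 1026). At the TGF-beta step 2 splits, the real one included, gave as many as the 163 higher and 90 lower genes. The other split gave 1193 in one direction and 1125 in the other, several times the real counts, which points to a structure of the samples. That split exchanged the displaced library of each group. The next highest gave 3 and 13. All these shares were under 0.05, but libraries of a donor deviated together, so splits that ignore the pairs do not exclude chance. For the numbers of lists chance cannot be excluded: 53 splits gave as many as the 7 of the first step (highest other 12). There were 29 as many as the 6 of the TGF-beta step (10) and 45 as many as the 8 against OKT3 (13). Among splits that part as many donor pairs as the real one, the highest higher and lower counts were 188 and 101 over 17 splits at the first step, 0 and 0 over 11 at the TGF-beta step and 0 and 1 over 19 against OKT3. Each of these sets is too small for a share under 0.05, so splits that respect the pairs cannot exclude chance. The larger counts came from splits that part fewer pairs. With the replicate block, 16 splits part all 5 pairs at the TGF-beta step, too few for a share under 0.05. The real counts were 423 and 426 (1 split as large for each, the real one) and the highest other 0 and 0.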
